A study of Mus musculus with 12 samples.

How the data were processed

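Total and polysome mRNA of mouse cortical neural progenitor cells treated with DMSO or Torin1 were sequenced in 12 libraries, 4 groups of 3 biological replicates, per the labels. Samples were grouped by their titles. The submitters' processing notes name STAR 2.7.9a, HTSeq 0.6.0 and the mm10 build, with no role or order. How the values of the deposited table were scaled is not given in the sources used here.

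The deposited table holds 53351 genes and 12 sample columns of a signal that is never below 0, and 0 other sample columns. The deposited signal is not read counts. In each library 99.65% to 100% of the nonzero values lay within 0.011 of a whole multiple of 1 step, and the number of steps in a column was at least 99.99% of the highest in every library, so a step is a fixed share of the column total and not a read. The depth in reads is therefore unknown, and no counting interval is given. A value of 0 can be a failed estimate, so genes listed at 0 in some libraries are given per library. All values are relative within a library, so a loss of polysome mRNA as a whole was not measured. Gene spans come from RefSeq's table for GRCm38, the assembly of mm10, in which 17436 of the 20240 genes tested were found by symbol.

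The design written before the data were examined assumed counts and named a count model. Since the values are not counts, the alternative test written beside it for such values was used. Values were divided by the column total and by an unweighted trimmed mean of log ratios (own code, trimmed shares of 0.3 of the ratios and 0.05 of the abundances at each end), and set to the mean column total. The factors averaged 1.11 for total DMSO, 1.08 for total Torin1, 0.835 for polysome DMSO and 1 for polysome Torin1. Genes with a deposited value of at least 1 in 3 or more libraries were tested. limma 3.58.1 in R 4.3.3 fitted log2(value + 1) over all 12 libraries with 4 group means and moderated variances that follow abundance. P-values were adjusted by Benjamini-Hochberg within each of 5 comparisons, at a threshold of 0.05. A fold on this scale understates the change of genes at very low values. Values in parts-per-million (ppm) are these scaled values, and expressed genes have a mean log2 value in ppm of at least 3.

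The genes named follow a rule. For Torin1 against DMSO in total mRNA, in polysome mRNA and in the interaction, it takes the 8 largest rises and the 8 largest falls among expressed genes past the threshold, without predicted, Rik, pseudogene or accession names. Every Torin1 library had to lie on the same side of every DMSO library or, for the interaction, the fold had to keep its sign without each replicate number. For polysome against total mRNA in DMSO it takes 6 and 6. From each of 29 gene lists it adds the 2 members with the largest fold past the threshold, or the most abundant member where none passed, and a fixed set of mTOR pathway, cell identity and reference genes. Lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists of a comparison.

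The fit was tested on simulated data of 20240 genes. Changes were set only in expressed genes, and noise was drawn independently for each gene, with the same spread in all 12 libraries. Recovery at lower abundance, with correlated genes and with a spread that differs between groups was therefore not tested. Of 100 genes changed 1.5-fold it recovered 68 in total and 71 in polysome mRNA, and of 100 changed 2-fold it recovered 94 and 93. It also called 6 unchanged genes in total and 11 in polysome mRNA. Alternatives were 4 other scalings, other filters, a pseudocount of 0.1, fits of the compared groups alone, blocks, each library and each replicate number left out, and a minimum of 1.5-fold. A filter at 1 ppm, the lists without total Torin1 replicate 2, other splits that keep the 2 libraries of a culture together, the lists with the cultures as blocks, and ribosomal protein genes summed with entries named as their copies were chosen after seeing the data.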

Results

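The series measured mRNA abundance in wild-type mouse cortical neural progenitor cells, taken from the embryonic cortex (E13.5) and kept overnight in culture. Cells received DMSO, the solvent control, or 250 nM Torin1, an inhibitor of the kinase mTOR, for 2 h. Cycloheximide at 100 ug/ml for 5 min then held ribosomes on their mRNAs. From each lysate 10% was kept as total mRNA. The rest was separated on a sucrose gradient, and the fractions with more than 3 ribosomes per mRNA gave the polysome mRNA. The 12 libraries form 4 groups of 3 biological replicates, namely total and polysome mRNA from DMSO and from Torin1 cells. The deposited values are abundances on a scale of each library and not reads, so the depth in reads is unknown. Column totals ran from 14341674 to 19201406. Values below are rescaled abundances on a parts-per-million scale (ppm), as mean ± SD over n = 3 libraries. Folds are on the log2(value + 1) scale, with their standard error. Within groups Pearson's r over 9217 expressed genes lay between 0.975 and 0.992, a correlation across genes, which are not independent replicates.

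The total mRNA comparison asked which transcripts changed in amount after 2 h of mTOR inhibition. Of 36 immediate early and ERK feedback genes 21 rose, with an adjusted p = 0.0543 with an estimated correlation, and of 44 FOXO targets and growth factor receptor feedback genes 16 rose. Of 38 G1/S and DNA replication genes 11 fell, both E cyclins among them, and of 48 ATF4, amino acid and one-carbon genes 8 fell, with an adjusted p = 0.143 with an estimated correlation. Fos, an AP-1 transcription factor on chromosome 12 from 85473890 to 85477274 (GRCm38), went from 13.1 ± 1.18 to 29.5 ± 1.10 ppm, a log2 fold of 1.17 ± 0.09 (limma, adjusted p = 7.98e-05). Sesn2, a leucine-binding inhibitor of mTORC1 signalling on chromosome 4 from 132492804 to 132510456, went from 13.7 ± 0.95 to 5.94 ± 0.189 ppm, a log2 fold of -1.20 ± 0.13 (limma, adjusted p = 0.000446).

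The immediate early and ERK feedback list, whose genes respond within minutes to growth signals, had 21 that rose and 1 that fell (23 and 1 adjusted over the list alone), with a median log2 fold of 0.59. With fry the adjusted p of this list was 0.000107. Spry1, a feedback inhibitor of receptor tyrosine kinases, rose by a log2 fold of 1.26, the orphan nuclear receptor gene Nr4a2 by 1.32 ± 0.10 and the activity-regulated Npas4 by 1.90 ± 0.20. The 1 that fell was Jund, an AP-1 subunit, with a log2 fold of -0.53 ± 0.12. Of 44 FOXO targets and growth factor receptor feedback genes, 16 rose and 1 fell (22 and 2 adjusted over the list alone), with a median of 0.28 and an adjusted p = 0.0231 with an estimated correlation. The 1 that fell, Erbb2, a receptor tyrosine kinase gene named after its values were seen, had -0.46 ± 0.11. Irs2, an insulin receptor substrate on chromosome 8 from 10984681 to 11008929, went from 16.6 ± 0.222 to 36.3 ± 0.618 ppm. Foxo1, a transcription factor held out of the nucleus by insulin signalling, had a log2 fold of 1.18 ± 0.17, and Klf4, a zinc finger transcription factor gene, had 1.75 ± 0.24 from a level of 1.95 ± 0.373 ppm.

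Of 38 G1/S and DNA replication genes, 11 fell and 1 rose (19 and 2 adjusted over the list alone), with a median log2 fold of -0.27 and an adjusted p = 0.0214 with an estimated correlation. Ccne2 and Ccne1, the E cyclins of S phase entry, went from 19.4 ± 1.96 to 8.91 ± 0.925 and from 15.3 ± 1.26 to 7.77 ± 2.22 ppm. The 1 that rose, the replicative helicase gene Mcm7, named after its values were seen, had a log2 fold of 0.23 ± 0.06. Of 48 ATF4, amino acid and one-carbon genes, 8 fell and 0 rose (8 and 0 adjusted over the list alone), with a median of -0.09. Chac1, which degrades glutathione, went from 14.7 ± 0.53 to 6.32 ± 1.30 ppm. Of 60 ribosome biogenesis genes, 9 fell and 0 rose (9 and 1 adjusted over the list alone), with an adjusted p = 0.0543 with an estimated correlation, and Bysl, a factor of small subunit assembly, had a log2 fold of -0.65 ± 0.09. Of 37 cholesterol biosynthesis and SREBP target genes, 6 fell and 0 rose (8 and 0 adjusted over the list alone), with an adjusted p = 0.23 with an estimated correlation. Of 78 mitochondrial ribosomal protein genes, 9 fell and 0 rose (12 and 0 adjusted over the list alone), with an adjusted p = 0.49 with an estimated correlation. The phosphatase gene Pgp, the sulfotransferase gene Gal3st3, the Ras association domain gene Rassf7 and the neddylation factor gene Dcun1d4 were also among the 8 largest falls, with log2 folds from -1.14 to -1.02.

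Of 31 radial glia and apical progenitor genes, 12 rose and 0 fell (13 and 0 adjusted over the list alone), with an adjusted p = 0.0769 with an estimated correlation. Hopx, a homeodomain gene, had a log2 fold of 0.70 ± 0.09 and Hes1, a Notch target, 0.66 ± 0.10. Sox2, a progenitor transcription factor, had 0.26 ± 0.06, a call lost whichever of the 6 total libraries was left out (highest adjusted p = 0.076, without total DMSO replicate 3). Of 15 intermediate progenitor genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone), with an adjusted p = 0.154 with an estimated correlation. Among them Btg2, an antiproliferative gene also in the immediate early list, had 0.69 ± 0.06, the proneural Neurog2 0.57 ± 0.10 and Eomes, a T-box factor gene, 0.43 ± 0.07. Of 35 neuronal genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone), with an adjusted p = 0.0769 with an estimated correlation. The 1 that fell, the zinc finger gene Scrt1, named after its values were seen, had -0.49 ± 0.08. The transcription factor genes Bhlhe22 and Mef2c went from 77.1 ± 2.45 to 157 ± 8.61 and from 40.7 ± 1.02 to 73.6 ± 5.47 ppm. Of 17 interneuron and ventral forebrain genes, 6 rose and 0 fell (8 and 0 adjusted over the list alone), with an adjusted p = 0.0214 with an estimated correlation, and Sp8, a zinc finger transcription factor gene, had a log2 fold of 0.92 ± 0.11. Of 25 endothelial, mural and meningeal genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.36 and an adjusted p = 0.0361 with an estimated correlation. They were the collagen genes Col1a1, from 3.67 ± 0.204 to 7.98 ± 0.675 ppm, Col1a2 and Col3a1, and the claudin gene Cldn5, named after its values were seen, and the call on Col3a1 was lost without each of 4 of the 6 libraries (highest adjusted p = 0.104, without total Torin1 replicate 3). Of 11 oligodendrocyte lineage and astrocyte genes, 1 rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 0.27 and an adjusted p = 0.0736 with an estimated correlation. That 1 was Olig2, a call lost without each of 4 of the 6 libraries (highest adjusted p = 0.0634, without total Torin1 replicate 3). Both lists hold Pdgfra and Cspg4, and the FOXO target list holds Pdgfra too. The transcriptional regulator genes Prdm8, Zfp608 and Zfp703 and the cell adhesion gene Flrt3 were among the 8 largest rises, with log2 folds from 1.18 to 1.35. Of 66 lysosome and v-ATPase genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone), with an adjusted p = 0.0214 with an estimated correlation, and Hexa, a lysosomal hexosaminidase gene, had 0.61 ± 0.11. The others were Naglu, a lysosomal glycosidase gene, whose call was lost without each of 4 of the 6 libraries (highest adjusted p = 0.0596, without total DMSO replicate 1), and the cathepsin gene Ctsa and the progranulin gene Grn, named after their values were seen. Differences did not pass for the progenitor factor gene Pax6 (log2 fold 0.18 ± 0.12), the neuronal tubulin gene Tubb3 (-0.08 ± 0.08), the D cyclin gene Ccnd1 (-0.05 ± 0.06), the lysosomal membrane gene Lamp1 (0.13 ± 0.06) and Mtor itself (-0.09 ± 0.11).

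In limma's test 1513 of 20240 genes passed an adjusted p of 0.05, 673 higher and 840 lower. The count was 720, 772 and 811 without total DMSO replicates 1, 2 and 3, 888, 773 and 756 without total Torin1 replicates 1, 2 and 3, and 841 with scaling to the column total alone, which ended the calls on Sox2, Eomes, Olig2, Naglu, Eef2 and Pabpc1. The total Torin1 library of replicate 2 stood apart, with 2061 ppm of the noncoding Rn7sk against 38.2 to 181 in the other 5 total libraries. Without it the genes higher and lower numbered 19 and 0 for immediate early genes, 12 and 0 for FOXO targets, 0 and 10 for G1/S, 0 and 5 for ATF4 genes, 0 and 4 for ribosome biogenesis, 0 and 2 for cholesterol genes and 0 and 3 for mitochondrial ribosomal proteins. They numbered 6 and 0 for radial glia, 5 and 0 for intermediate progenitors, 9 and 1 for neurons, 5 and 0 for interneurons, 2 and 0 for endothelial genes, 1 and 0 for oligodendrocyte and astrocyte genes and 2 and 1 for lysosome genes.

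The polysome mRNA comparison asked which transcripts gained or lost share among mRNAs with more than 3 ribosomes. Of 82 cytosolic ribosomal protein genes, 80 were lower with Torin1 and 0 higher (82 and 0 adjusted over the list alone), with a median log2 fold of -1.17, an SD over genes of 0.31 and an adjusted p = 0.0802 with an estimated correlation. With fry the adjusted p of this list was 7.94e-05. Rps19, a small subunit protein gene on chromosome 7 from 24884592 to 24889811, went from 1289 ± 210 to 364 ± 76.8 ppm, a log2 fold of -1.83 ± 0.14 (limma, adjusted p = 2.3e-05). Together these mRNAs made up 19.3 ± 1.4% of polysome signal in DMSO and 10.6 ± 0.917% in Torin1. In total mRNA their share was 12.9 ± 0.0577% and 13.4 ± 0.693%, and limma called 0 of the 82 there (2 at an unadjusted p under 0.05), with a median of 0.09.

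Rps27 went from 6874 ± 1430 to 1952 ± 450 ppm in polysome mRNA and Rps12 from 3248 ± 414 to 956 ± 140. Rps7, Rpl32, Rpl17 and Rps20 had log2 folds from -1.61 to -1.52. Rps27rt, a copy of Rps27, had -1.74 ± 0.19 and can share its reads. Rplp0, of the ribosomal stalk, went from 1449 ± 100 to 589 ± 72.1 ppm and Rps6, a substrate of S6 kinase, from 2443 ± 368 to 1139 ± 180. Ribosomal protein genes have many pseudogene copies, so single values of these genes are uncertain. Of 31 other mRNAs listed in advance as having a 5' terminal oligopyrimidine (TOP) motif, 12 fell and 1 rose (17 and 3 adjusted over the list alone), with a median of -0.29 and an adjusted p = 0.103 with an estimated correlation. The 1 that rose was Eif3a, an initiation factor gene, with 0.70 ± 0.08. The motif itself was not examined in the listed genes. Tpt1, the translationally controlled tumour protein gene, went from 1760 ± 163 to 668 ± 108 ppm, and Ybx1, a cold shock domain protein gene, from 874 ± 33.4 to 380 ± 10.2. The elongation factor gene Eef1a1 had a log2 fold of -0.93 ± 0.12 and the poly(A)-binding protein gene Pabpc1 -0.60 ± 0.09. Eef2, another elongation factor gene, had -0.05 ± 0.08 and did not pass (limma, adjusted p = 0.771). In total mRNA 4 of the 31 rose and 0 fell (4 and 0 adjusted over the list alone), with an adjusted p = 0.143 with an estimated correlation. They were Vim, an intermediate filament gene also in the radial glia list, with 0.60 ± 0.09, Eef2 with 0.46 ± 0.08, the initiation factor gene Eif4b, named after its values were seen, with 0.38 ± 0.06, and Pabpc1 with 0.43 ± 0.09. The call on Pabpc1 was lost without each of 2 of the 6 total libraries (highest adjusted p = 0.0566, without total DMSO replicate 2). Of 12 snoRNA host genes of the TOP class, 2 fell and 0 rose in polysome mRNA (3 and 0 adjusted over the list alone). Their median was 0.01, with an adjusted p = 0.948 with an estimated correlation.

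Of 78 mitochondrial ribosomal protein genes, 17 fell and 0 rose (25 and 0 adjusted over the list alone), with an adjusted p = 0.26 with an estimated correlation and a median of -0.22 that was 0.05 with scaling to the column total alone. Of 76 nuclear-encoded oxidative phosphorylation genes, 13 fell and 1 rose (16 and 1 adjusted over the list alone), with an adjusted p = 0.484 with an estimated correlation and a median of -0.26 that was 0.01 with that scaling. The 1 that rose was Sdha, a respiratory complex gene named after its values were seen. Atp5k and Uqcrh had the largest folds of the list, and each call was lost without each of 4 of the 6 polysome libraries. In polysome Torin1 replicate 3 both lay within the DMSO range. Uqcrh was at 1348 ppm there against 1264 to 1738 in polysome DMSO, and Atp5k at 1267 against 1147 to 1744. Of G1/S genes, 12 fell and 1 rose (15 and 3 adjusted over the list alone), with an adjusted p = 0.0802 with an estimated correlation and a median of -0.22 that was 0.04 with that scaling. Mcm7 was again the 1 that rose, and Ccne1 had a log2 fold of -0.86. Of ATF4 genes, 6 fell and 5 rose (8 and 5 adjusted over the list alone), with an adjusted p = 0.58 with an estimated correlation. Among them Sesn2 had -1.37 ± 0.13. For ribosome biogenesis 13 fell and 4 rose (14 and 5 adjusted over the list alone), with an adjusted p = 0.123 with an estimated correlation. For cholesterol genes 6 fell and 1 rose (8 and 2 adjusted over the list alone), with an adjusted p = 0.618 with an estimated correlation.

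Of immediate early genes, 22 rose and 1 fell in polysome mRNA (23 and 1 adjusted over the list alone), with an adjusted p = 0.0802 with an estimated correlation. Jund was again the 1 that fell, and Fos went from 8.75 ± 0.561 to 24.9 ± 2.18 ppm. Of FOXO targets, 18 rose and 1 fell (19 and 1 adjusted over the list alone), with an adjusted p = 0.0375 with an estimated correlation. Erbb2 was again the 1 that fell. The receptor genes Sstr1 and Prokr2, the activin antagonist gene Fst, Tcim, Flrt3, Nr4a2 and Zfp608 had log2 folds from 1.21 to 1.44. Of radial glia genes, 13 rose and 0 fell (15 and 0 adjusted over the list alone), with an adjusted p = 0.0934 with an estimated correlation. Of intermediate progenitor genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone), with an adjusted p = 0.123 with an estimated correlation. Of neuronal genes, 11 rose and 1 fell (13 and 2 adjusted over the list alone), with an adjusted p = 0.0934 with an estimated correlation, and Scrt1 was again the 1 that fell. Of interneuron genes, 6 rose and 0 fell (8 and 0 adjusted over the list alone), with an adjusted p = 0.0375 with an estimated correlation. Of endothelial, mural and meningeal genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone), with a median of 0.27 and an adjusted p = 0.0934 with an estimated correlation. They were Col1a1 with a log2 fold of 1.03 ± 0.14, Col1a2 with 1.05 ± 0.155 and Cldn5. Of oligodendrocyte lineage and astrocyte genes, 1 rose and 0 fell (2 and 0 adjusted over the list alone), with a median of 0.23 and an adjusted p = 0.0934 with an estimated correlation, that 1 being Aldh1l1, a folate enzyme gene, with 0.59 ± 0.115. Of lysosome genes, 8 rose and 1 fell (8 and 2 adjusted over the list alone), with an adjusted p = 0.0375 with an estimated correlation. The 1 that fell was Tfeb, the lysosomal regulator gene, with -1.26 ± 0.36 from 1.41 ± 0.0554 ppm, a call lost whichever of the 6 polysome libraries was left out (highest adjusted p = 0.121, without polysome DMSO replicate 3). Bhlhe22 went from 71.7 ± 1.46 to 142 ± 4.13 ppm. Deptor, an inhibitory partner of mTOR, had a log2 fold of 1.10 ± 0.15 and Atg14, an autophagy initiation factor gene, 1.12 ± 0.15.

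**Figure D1:**
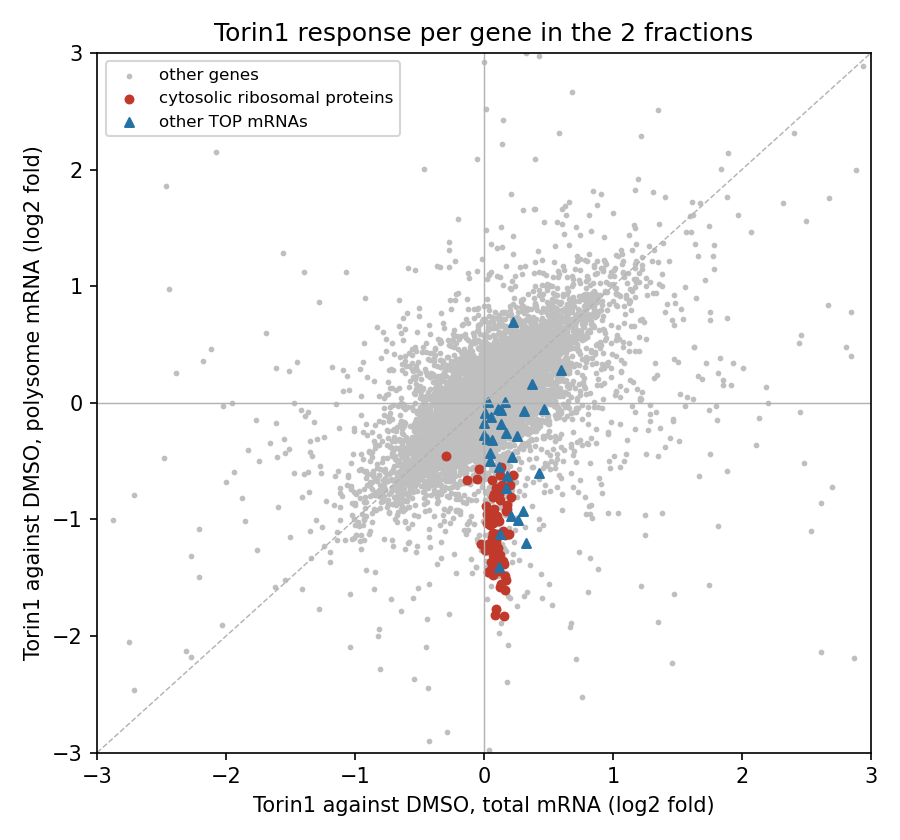
Log2 fold of Torin1 against DMSO in total mRNA (x axis) and in polysome mRNA (y axis) for 13532 genes with a mean of at least 1 ppm, of which 57 lie outside the axes; the dashed line marks equal folds. Cytosolic ribosomal protein genes (red points) have a median of 0.09 on the x axis and -1.17 on the y axis, and other TOP mRNAs (blue triangles) 0.16 and -0.29.

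In limma's test 2162 of 20240 genes passed in polysome mRNA, 892 higher and 1270 lower. Of the 673 genes higher in total mRNA, 435 were also higher and 7 lower in polysome mRNA, and of the 840 lower genes 584 were also lower and 0 higher. Both comparisons draw on the same cultures, so this overlap was not tested against chance. Across 9217 expressed genes their folds correlated with r = 0.546, and with r = 0.753 over 8833 genes without listed ribosomal protein and other TOP genes and entries named as copies or predicted genes, values across genes, which are not independent replicates. Scaling to the column total alone moved the median of these genes from -0.06 to 0.20, the split to 2911 higher and 329 lower, and the ribosomal protein median to -0.91. The count was 1350 without polysome DMSO replicate 1, 1279 without polysome DMSO replicate 3 and 404 with the 6 polysome libraries fitted alone, which ended 38 of 72 calls on named genes, among them Eef1a1, Pabpc1, Ccne1, Tfeb and Aldh1l1. The scaling to the column total alone ended those on Pabpc1, Ccne1 and Tfeb too. Of the 12 libraries, polysome Torin1 replicate 3 deviated the most from its own group. Its log2 differences had an SD of 0.344 over expressed genes, against 0.298 for total Torin1 replicate 2. Its correlation with polysome Torin1 replicate 1 was the lowest within a group, r = 0.9748. The count was 2534 without polysome Torin1 replicate 1 and 2889 without replicate 3, and the list tests were not repeated without either.

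**Figure D2:**
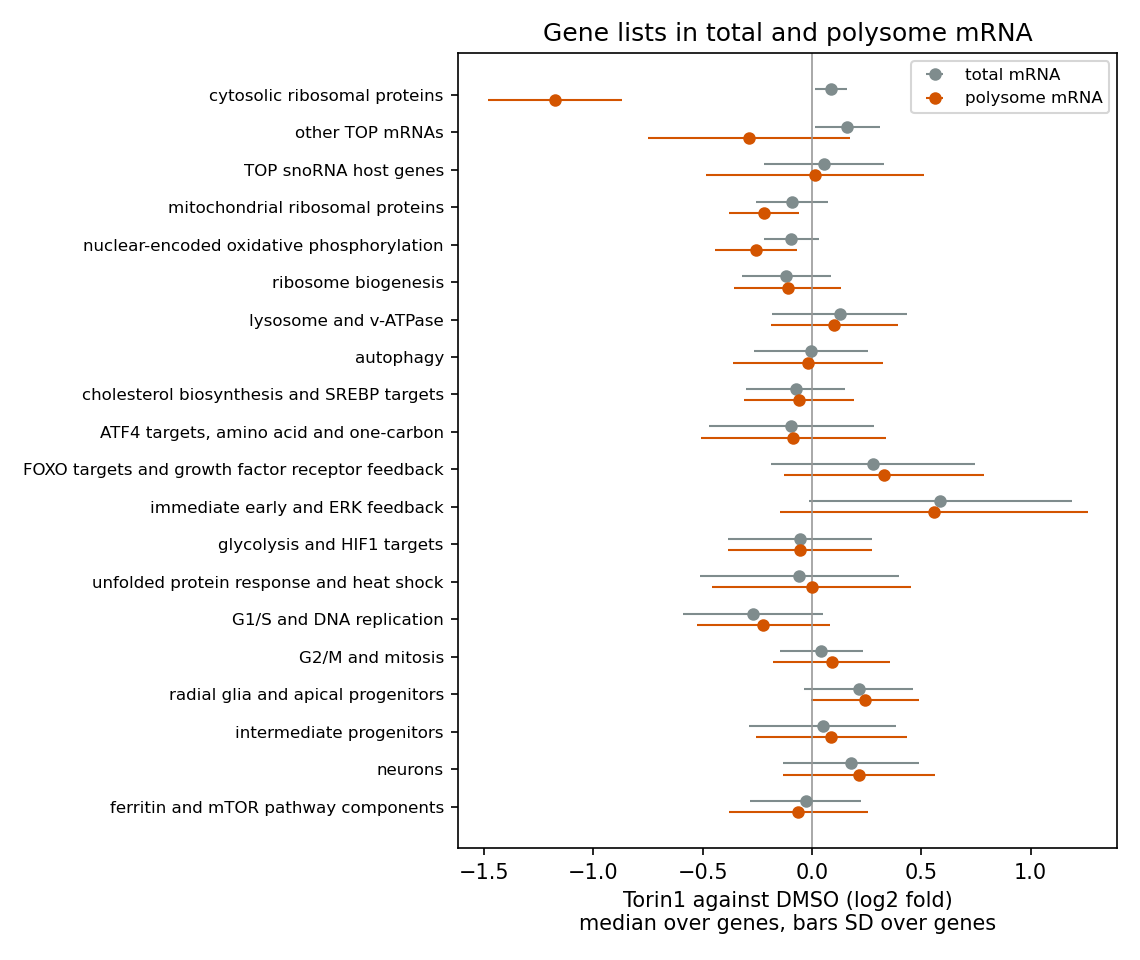
Median log2 fold of Torin1 against DMSO over the genes of each list shown, in total mRNA (grey) and polysome mRNA (orange). Bars are the SD over genes, not over libraries. Left out are the interneuron, Cajal-Retzius, blood, endothelial, microglia and oligodendrocyte lists. The lists of mitochondrially encoded genes, histones and nuclear and noncoding RNAs are left out too. The cytosolic ribosomal protein list has medians of 0.09 in total and -1.17 in polysome mRNA, and the immediate early list 0.59 and 0.56.

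The interaction asked whether the Torin1 effect differed between polysome and total mRNA, that is, whether polysome association changed beyond mRNA amount. Of the 82 cytosolic ribosomal protein genes, 65 fell and 0 rose (80 and 0 adjusted over the list alone), with a median log2 fold of -1.25, a ratio of 0.42, and an adjusted p = 0.0305 with an estimated correlation. Rps19 fell by 1.99 ± 0.20 on the log2 scale (limma, adjusted p = 0.00056), Rps27 by 1.91 and Rps12 by 1.86 ± 0.17. Of 31 other TOP mRNAs, 10 fell and 0 rose (19 and 1 adjusted over the list alone), with a median of -0.43 and an adjusted p = 0.0272 with an estimated correlation. With the 6 cultures as blocks, taken by treatment and replicate number, 48 of the 82 and 8 of the 31 fell and 0 rose (80 and 0, and 16 and 1, adjusted over the list alone), and the adjusted p = 0.223 with an estimated correlation for either list. The 10 were Ybx1, Tpt1, the elongation factor genes Eef1a1, Eef1b2 and Eef1g, the initiation factor genes Eif3f, Eif3h and Eif3k, Pabpc1 and the ribosome-bound Rack1, of which Eif3h and Eif3k did not pass with the blocks (adjusted p = 0.059 and 0.116).

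Rps7, Rpl32, Rps20 and Rpl17 had log2 folds from -1.77 to -1.68, Rplp0 had -1.43 ± 0.13 and Rps6 -1.25 ± 0.18. Ybx1 had -1.53 ± 0.23, Tpt1 -1.52 ± 0.16, Eef1a1 -1.23 and Pabpc1 -1.03. Eef2 had -0.51 ± 0.12 and did not pass (limma, adjusted p = 0.11). Limma called 0 of 12 snoRNA host genes of the TOP class (3 at an unadjusted p under 0.05). Their median was -0.11, with an adjusted p = 0.993 with an estimated correlation. Of the 140 genes that fell, 65 were listed ribosomal protein genes, 24 were entries named as copies of such genes, 10 were other TOP mRNAs, 30 were other predicted, Rik or pseudogene entries and 11 were other named genes. Rpl35a-ps2, Rpl35a-ps3, Rpl35a-ps4, Rpl35a-ps6 and Gm10243 had equal results (-1.142 ± 0.225), as did Gm13841 and Gm8210 (-1.394 ± 0.139), all named after their values were seen. The 140 are therefore not independent genes. Among the 11 were Ccni, a cyclin-like gene, with -0.79 ± 0.08, the respiratory supercomplex gene Cox7a2l with -1.27 ± 0.14 and Nme2, a nucleoside diphosphate kinase gene, with -0.78 ± 0.14, all named after their values were seen. The ATP synthase subunit gene Atp5g2 had -0.59 ± 0.09, a call lost without total DMSO replicate 2, total DMSO replicate 3 or total Torin1 replicate 3 (highest adjusted p = 0.0521, without the last). The 3 genes that rose were Srd5a1, a steroid reductase gene on chromosome 13 from 69573449 to 69611485, with 0.68 ± 0.13, and the G protein subunit gene Gng8 and the predicted gene Gm14439, both at low abundance and named after their values were seen. The call on Srd5a1 was lost with each of 11 of the 12 libraries left out (highest adjusted p = 0.109), the exception being polysome Torin1 replicate 3 (adjusted p = 0.0104). With the cultures as blocks none of these 3 rises passed in limma (adjusted p = 0.129 for Srd5a1, 0.212 for Gng8 and 0.0921 for Gm14439), nor did Nme2 (0.104) or Atp5g2 (0.0983).

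**Figure D3:**
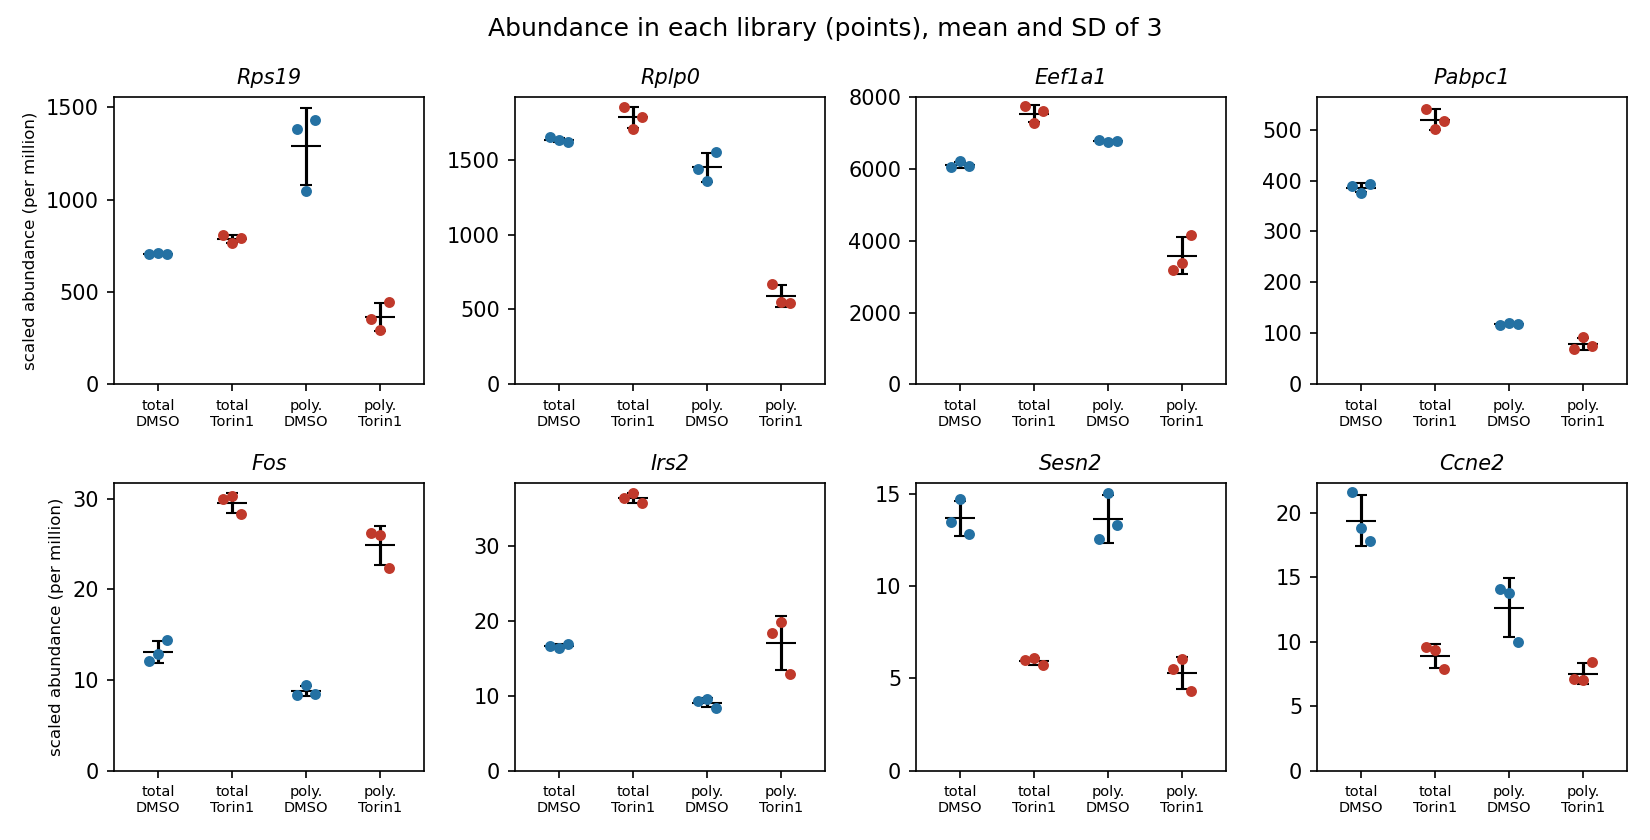
Abundance in ppm in each library (points, blue for DMSO and red for Torin1) of 8 genes, with mean and SD of 3 libraries as horizontal bar and error bar; y axes start at 0. Rps19 averages 708 and 789 ppm in total mRNA and 1289 and 364 in polysome mRNA for DMSO and Torin1, whereas Fos averages 13.1, 29.5, 8.75 and 24.9.

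Limma called 0 members in the interaction for immediate early genes (1 of 36 at an unadjusted p under 0.05), FOXO targets (0 of 44), G1/S (2 of 38), ATF4 genes (4 of 48), cholesterol genes (2 of 37) and lysosome genes (4 of 66). It also called 0 for radial glia (1 of 31), intermediate progenitors (0 of 15), neurons (3 of 35) and interneurons (0 of 17). Medians of these 10 lists lay between -0.02 and 0.07, or between 0.28 and 0.37 with scaling to the column total alone, with which camera at the preset correlation called 8 of the 10 higher. Sox2, Hes1, Eomes and Neurog2 had interactions from -0.14 to 0.08. Of mitochondrial ribosomal protein genes 0 of 78 were called by limma (5 at an unadjusted p under 0.05), with a median of -0.10 and an adjusted p = 0.942 with an estimated correlation. Of oxidative phosphorylation genes 1 of 76, Atp5g2, was called (1 adjusted over the list alone), with a median of -0.13 and an adjusted p = 0.942 with an estimated correlation. Camera also called the histone list, with 0 of 27 members called by limma (1 at an unadjusted p under 0.05), a median of -0.72 and an adjusted p = 0.942 with an estimated correlation, and the median was 0.04 without total Torin1 replicate 2. The medians of both mitochondrial lists were above 0 with scaling to the column total alone, at 0.20 and 0.17.

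In limma's test 143 of 20240 genes passed, 3 higher and 140 lower. The count was 0 without replicate 1 of all 4 groups (1222 at an unadjusted p under 0.05), 77 without replicate 2, 232 without polysome Torin1 replicate 3 and 92 with the 6 cultures as blocks, 0 higher and 92 lower (1134 at an unadjusted p under 0.05), of which 90 were among the 143. Scaling to the column total alone gave 32 higher and 119 lower, with the median of expressed genes at 0.30 and the calls on Pabpc1 and Atp5g2 lost. On simulated data the interaction test recovered 28 of 100 expressed genes changed 1.5-fold and 65 of 100 changed 2-fold, and called 6 unchanged genes. The simulated noise was independent and had the same spread in all 12 libraries.

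The comparison of polysome with total mRNA described which transcripts were over- or underrepresented on polysomes, first in DMSO cells. Of 82 cytosolic ribosomal protein genes, 79 were higher and 1, Rpsa, named after its values were seen, lower (79 and 1 adjusted over the list alone), with a median log2 fold of 1.01 and an adjusted p = 0.472 with an estimated correlation. Of 78 mitochondrial ribosomal protein genes, 76 were higher and 0 lower (76 and 0 adjusted over the list alone), with a median of 0.97 and an adjusted p = 0.15 with an estimated correlation. Of 76 oxidative phosphorylation genes, 75 were higher and 0 lower (75 and 0 adjusted over the list alone), with a median of 1.30 and an adjusted p = 0.161 with an estimated correlation. Of 15 mitochondrially encoded genes, 12 were lower and 0 higher (13 and 0 adjusted over the list alone), with an adjusted p = 0.26 with an estimated correlation.

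Pet100, an assembly factor of cytochrome c oxidase, went from 22.7 ± 0.977 ppm in total to 102 ± 19 in polysome mRNA, a log2 fold of 2.15 ± 0.14. The galectin gene Lgals1 went from 233 ± 6.65 to 992 ± 148 ppm, the cytochrome c oxidase gene Cox7a2 from 238 ± 1.66 to 978 ± 157 and the ATP synthase gene Atp5j2 from 258 ± 2.78 to 1055 ± 219. The histone gene Hist1h2ap had 2.05 ± 0.56. Another histone gene, Hist1h4n, had 2.41 ± 0.75, a call lost without total DMSO replicate 1 or 2 or polysome DMSO replicate 1 or 3 (highest adjusted p = 0.0803, without the last). The mitochondrial rRNA mt-Rnr2 was at 625 ± 33.5 ppm in total and 20.5 ± 4.4 in polysome mRNA, and mt-Atp8 at 40460 ± 1010 and 2844 ± 1340. mt-Co2 was listed at 51.8 ppm in polysome DMSO replicate 1 and at 0 in replicates 2 and 3. Of 18 nuclear and noncoding RNAs, 11 were lower and 0 higher (11 and 0 adjusted over the list alone), with an adjusted p = 0.15 with an estimated correlation. Malat1, a nuclear RNA on chromosome 19 from 5795690 to 5802672, was at 64.2 ± 5.96 and 6.04 ± 2.15 ppm. Rn7sk was at 92.8 ± 77 in total mRNA and listed at 1.19, 0 and 5.69 in the polysome libraries. Rn7s1 and Rn7s2, RNAs of the signal recognition particle, had equal values of 193 ± 177 and 2.89 ± 0.49, and reads cannot be assigned to either copy.

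Of 35 neuronal genes, 21 were lower and 4 higher (21 and 4 adjusted over the list alone), with a median of -0.42 and an adjusted p = 0.161 with an estimated correlation. The 4 higher were the stathmin genes Stmn1 and Stmn2, the growth cone gene Gap43 and Tubb3, of which Stmn2 and Gap43 were named after their values were seen. The nuclear factor I genes Nfib and Nfia had log2 folds of -1.81 ± 0.15 and -1.77 ± 0.10. The proliferation marker Mki67 had -2.24 ± 0.14 and the kinesin gene Cenpe -2.30 ± 0.18. Pabpc1 had -1.70 ± 0.09, the actin gene Actb -0.57 ± 0.10, the glycolytic gene Gapdh 0.50 ± 0.08 and Tubb3 0.50 ± 0.08. Of 66 lysosome genes, 30 were higher and 5 lower (32 and 6 adjusted over the list alone), with an adjusted p = 0.0334 with an estimated correlation and a median of 0.28 that was -0.13 with scaling to the column total alone. The 5 lower were Atp6v1a, Fnip1, Fnip2, Ids and Npc1, named after their values were seen. Of 12 snoRNA host genes of the TOP class, 7 were lower and 1, Snhg3, higher (8 and 1 adjusted over the list alone), with an adjusted p = 0.545 with an estimated correlation. Camera's calls at the preset correlation were also lost for FOXO targets (adjusted p = 0.523 with an estimated correlation), autophagy (0.15), glycolysis (0.576), histones (0.612) and microglia genes (0.545).

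In limma's test 8331 genes passed in DMSO, 4416 higher and 3915 lower, and 8063 in Torin1, 4192 higher and 3871 lower. Scaling to the column total alone gave 1853 higher and 6708 lower in DMSO and moved the median of 9217 expressed genes from 0.15 to -0.26, while the medians of the ribosomal protein, mitochondrial ribosomal protein and oxidative phosphorylation lists were 0.60, 0.56 and 0.89 and the calls on Gapdh and Tubb3 were lost.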

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

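The tests on other short mRNAs, with copies summed and with cultures split whole, and the list tests with cultures as blocks, were chosen after the result was seen.

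The response to Torin1 differed between polysome and total mRNA for 143 genes, for the cytosolic ribosomal protein list, with a median interaction of -1.253 (log2), and for the other TOP mRNAs, with a median of -0.435 (adjusted p = 0.223 for either list with an estimated correlation and the cultures as blocks). The 143 hold entries that can share reads, some with equal values, so they are not independent genes. Each lysate gave both a total and a polysome library, so the 6 cultures, taken by treatment and replicate number, make 10 splits, too few for a share under 0.05, of which 1, the real one, gave as many genes and the highest other gave 6. In 100 splits within each fraction, which break up the cultures, 1 gave as many, the real one, and the highest other gave 7. The count was 92 with the cultures as blocks, 0 higher and 92 lower (1134 at an unadjusted p under 0.05), and 0 without replicate 1 of all 4 groups (1222 at an unadjusted p under 0.05 in limma).

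For the fall of ribosomal protein mRNAs, the values argue against scaling and reads shared with copies as the whole cause. Under 4 other scalings the median stayed at or below -0.951, and with entries named as copies summed it was -1.263 (290 entries added, 65 genes lower). Another explanation is a loss of short mRNAs from polysomes as a class. The mitochondrial ribosomal protein and oxidative phosphorylation lists, taken here as other short mRNAs, had medians no lower than -0.129. Camera at the preset correlation still called both lower (adjusted p = 0.00154 and 4.22e-05), and transcript length was not analysed. These lists therefore argue against short mRNAs only as the whole cause, and a part played by length stays open. The other TOP mRNAs fell in 10 of 31 genes against 65 of 82. The motif was not examined in these 31, so members without it may be among them. Of 12 snoRNA host genes of the TOP class limma called 0 (3 at an unadjusted p under 0.05), with a median of -0.106. Differences between these lists were not tested. What links the Torin1 treatment to the fall stays open and untested, since transcript starts were not analysed here, and values relative within a library leave a change of polysome mRNA as a whole open.

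For the other comparisons the 6 libraries make 10 splits, too few for a share under 0.05. In each, 1 of 10 gave as many genes, the real split, with 1513 in total mRNA (highest other 6), 2162 in polysome mRNA (highest other 430), 8331 for polysome against total in DMSO (highest other 3) and 8063 in Torin1 (highest other 4).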

How the results depend on the processing

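The filter at 1 ppm, the copies summed, the splits of whole cultures, the list tests with cultures as blocks and the list tests without total Torin1 replicate 2 were chosen after seeing the data. The ribosomal protein median of the interaction lay between -1.374 and -0.951 under every alternative tried. Scaling to the column total alone gave 841 genes in total mRNA, a split of 2911 higher and 329 lower in polysome mRNA, 32 and 119 in the interaction and 1853 and 6708 for polysome against total in DMSO. It turned 4 genes of that last comparison, Neurog2 from 0.05 to -0.37 (adjusted p = 0.0388), Hes1 from 0.01 to -0.40 (adjusted p = 0.0361), Eef1a1 from 0.15 to -0.26 (adjusted p = 0.034) and Ccnd1 from 0.13 to -0.28 (adjusted p = 0.0482). It also ended 38 of 227 calls on named genes, 13 in total mRNA, 15 in polysome mRNA, 2 in the interaction and 8 for polysome against total. Fits of the compared groups alone ended 44 of 211, 38 of them in polysome mRNA, and gave 2515 genes in total and 404 in polysome mRNA. The main counts were 1513 and 2162, so fewer libraries alone do not account for both. The main fit shares 1 spread among the 4 groups. Over expressed genes, the SD of a library's log2 differences from its group was 0.26 to 0.344 in polysome Torin1. It was 0.204 to 0.219 in polysome DMSO, 0.202 to 0.298 in total Torin1 and 0.189 to 0.204 in total DMSO. The shared spread can thus be too narrow for polysome Torin1, which was not tested. A minimum of 1.5-fold, which by construction calls fewer, gave 654 in total mRNA, 960 in polysome mRNA, 5465 for polysome against total in DMSO and 5078 in Torin1. With libraries or replicate numbers left out, which also leaves fewer samples, counts ranged from 110 to 888 in total mRNA, 504 to 2889 in polysome mRNA, 0 to 232 in the interaction, 6471 to 7719 for polysome against total in DMSO and 6034 to 7964 in Torin1. Without polysome Torin1 replicate 3 counts rose from 2162 to 2889 in polysome mRNA and from 143 to 232 in the interaction, so fewer samples alone do not account for the range. An arm left with 2 libraries shares the spread of the other groups. The lists called went from 19 to 5 in total mRNA, 16 to 3 in polysome mRNA, 5 to 2 in the interaction and 13 to 1 for polysome against total with an estimated correlation. With fry they were 16 in total mRNA, 16 in polysome mRNA, 2 in the interaction and 23 for polysome against total. With scaling to the column total alone they were 17 in the interaction, 14 higher and 3 lower, against 0 higher and 5 lower with the main scaling. Without total Torin1 replicate 2 they were 18 in total mRNA and 4 in the interaction. Except for the minimum fold, which calls fewer by construction, the cause of these changes was not tested.

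Each lysate gave a total and a polysome library, but the labels do not say that equal numbers mark 1 lysate, and deviations of the 6 same-numbered total and polysome pairs of a treatment correlated by -0.0858 to 0.0819. Nothing in the labels pairs DMSO with Torin1 cultures. Of all 18 same-numbered correlations 2 were above 0.1 (range -0.231 to 0.329, others -0.282 to 0.343) and 1 of 12 libraries correlated best with its own number, a hint from the data that leaves the pairing within lysates open. With the replicate block the counts were 1284, 1976, 148, 8227 and 7927 for total, polysome, the interaction and polysome against total in DMSO and Torin1. With the cultures as block they were 92 (0 higher, 92 lower), 7917 and 7626 for the last 3, and the calls on Srd5a1, Rps27rt and Atp5g2 in the interaction were lost among named genes. Of the named genes called, 41 of 62, 57 of 72, 14 of 16 and 72 of 77 kept their call without each single library (total, polysome, interaction, polysome against total in DMSO), and 0 changed sign. Without replicate numbers 1, 2 and 3 in turn, 97, 86 and 62 of the 227 calls were lost. The DESeq2 and limma-voom tests planned for counts were not run, as the values are not counts, and the unknown depth limits what low genes can show.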

Other observations

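Both tests on the library that stood apart use its own values, and the one on RNA without poly(A) tails was chosen after the result was seen.

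In total mRNA, of 9 Cajal-Retzius genes 1 rose (2 adjusted over the list alone), Ebf3, a call lost whichever total library was left out (highest adjusted p = 0.0957, without total DMSO replicate 3). Limma called 0 of 11 blood genes (1 at an unadjusted p under 0.05) and 0 of 18 microglia and macrophage genes (3 at an unadjusted p under 0.05), with an adjusted p = 0.486 with an estimated correlation. Of 34 glycolysis and HIF1 target genes 1 rose and 4 fell (1 and 4 adjusted over the list alone), and the riser Ndrg1 had a log2 fold of 0.52 ± 0.08. Of 31 unfolded protein response and heat shock genes 1 rose and 4 fell (1 and 6 adjusted over the list alone). Of 40 autophagy genes 3 rose and 2 fell (3 and 3 adjusted over the list alone), and of 37 G2/M genes 1 rose and 2 fell (1 and 2 adjusted over the list alone). Deptor went from 10.5 ± 1.05 to 19.1 ± 1.76 ppm and Pdcd4, a translation inhibitor gene, had 0.56 ± 0.07, among 2 higher and 2 lower of 34 mTOR pathway and ferritin genes (2 and 3 adjusted over the list alone). Risers outside the naming rule were Calcoco1 and Pik3c3 among autophagy genes, and fallers were Tpi1, Rpia, Creld2, Dnajb1, Aurka, Larp1 and Rraga, all named after their values were seen. Among those the rule names, the calls on P4ha2, Dnajc3, Atg4d, Atg5, Ndc80 and Tacc3 were each lost without at least 3 of the 6 total libraries, with the highest adjusted p = 0.155 for P4ha2 without total Torin1 replicate 3. Without total Torin1 replicate 2, the genes that limma called higher and lower numbered 0 and 0 for Cajal-Retzius, 1 and 1 for glycolysis, 1 and 3 for unfolded protein response, 0 and 0 for autophagy, 0 and 0 for G2/M and 2 and 1 for mTOR pathway genes. Neat1, a nuclear noncoding RNA, was at 0.854 ± 0.463 and 3.48 ± 0.855 ppm, a call lost without total Torin1 replicate 2 (adjusted p = 0.0571).

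Across 8643 expressed protein-coding genes, the log2 fold of polysome against total mRNA in DMSO fell with the genomic span of the gene (Spearman's rho = -0.551, and -0.515 in Torin1). In 4 groups by span, at median spans of 5.55, 16.2, 35.2 and 103 kb, the median log2 fold was 0.59, 0.28, 0.01 and -0.35. For the interaction rho was 0.141. Genes are not independent replicates, and span is not transcript length, which was not analysed here.

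The total Torin1 library of replicate 2 held more of many RNAs that lack poly(A) tails, such as 2061 ppm of Rn7sk against 80.8 and 40.7 in the other total Torin1 libraries. Over 22 small structured RNAs and histones its median log2 difference from those 2 libraries was 3.23, with 21 above, so a library with more RNA without poly(A) tails may account for it. On 773 genes called without it, its position between DMSO (0) and the other Torin1 libraries (1) was 0.693, which argues against a wrong treatment label. The DMSO libraries, each set against the others, lay at -0.0165 to 0.0096. They helped to choose these genes, so their range is no reference for a library left out. Of 27 replication-dependent histone genes 3 rose in total mRNA, with a median log2 fold of 1.02 and an adjusted p = 0.394 with an estimated correlation, and 2 rose without this library, with a median of 0.16. No biological explanation was tested.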
